A study of Mus musculus with 24 samples.

How the data were processed

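The series profiles mouse retina (strain C57/Bl6N) by RNA sequencing at 12 ages, 4 embryonic and 8 postnatal, with 2 libraries per age and 24 in all. Per the labels, retinas were excised and frozen, total RNA was isolated with Trizol, RNA quality was assessed on a Nano kit, and directional libraries of PolyA RNA were made with a modified Illumina mRNA kit from 100 ng of RNA at E11 and E12 and 1 µg at the other ages. The labels do not say whether replicates are separate animals, pools or litters, so the p-values measure the spread between these samples only. Sex, sequencing dates and batches are not given in the sources used here.

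The authors deposited estimated counts per Ensembl transcript and per Ensembl gene, and per the submitters' processing notes kallisto 0.42.4, edgeR 3.13.9 and genome build GRCm38.p5 were used, without a role for each. How transcript estimates were summarised to genes is not given in the sources used here. The gene table holds 45594 genes, and 113468 transcripts were quantified. For genes with a single transcript above a minimum count, gene values were checked against the transcript values. Their ratio had a median of 0.998 (5th to 95th percentile 0.942 to 1.03) over 77423 values. Genes with several transcripts were not checked in this way. Library totals of genes and transcripts were equal. Library totals ran from 24567532 (P2 replicate 1) to 35898879 counts (P28 replicate 2). The authors also deposited log2 changes of each age against E11 with a p-value, an adjusted p-value and a cluster number for 12718 genes in 36 clusters, per the file headers. The method of adjustment and of clustering is not given in the sources used here, and the highest adjusted p in that table is 0.00999. Of its 12718 genes all were tested here and 12689 passed the omnibus thresholds, the log2 changes of E16 vs E11 had r = 0.985 across these genes with those computed here, and 12507 had the same sign. The clusters and the deposited normalized CPM table were not used here, since CPM values were computed from the gene counts.

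Counts were rounded to whole numbers and analysed with edgeR 4.0.16 and limma 3.58.1 in R 4.3.3. Genes were kept with filterByExpr by stage at a minimum count of 10, which left 21858, and libraries were scaled by TMM. A quasi-likelihood model with 1 coefficient per stage was fitted to all 24 libraries (12 residual degrees of freedom). Genes were called where the Benjamini-Hochberg adjusted p was under 0.05 and the change at least 2-fold, and in the omnibus test of all stages where the range of fitted stage means was at least 2-fold. Comparisons were 3 windows (E16 vs E11, P6 vs E16, P28 vs P6) and 11 steps between neighbouring stages. Standard errors (SE) are the absolute log2 change divided by the square root of the F statistic. For a gene without counts in a stage, a lower bound of the fold was computed against a floor of 3 counts over the stage's libraries. Principal components were computed on log2 CPM with a prior count of 2.

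For 29 gene lists (516 of 520 symbols tested) in the 3 windows, camera with an inter-gene correlation of 0.01 was run, with Benjamini-Hochberg adjustment over the 87 tests. Estimated correlations were often far larger (0.263 for rod genes in P6 vs E16), so very small camera p-values overstate the certainty. Counts of called members were taken over all genes and again with adjustment over the list alone. The stage with the highest mean was counted per list without a test. The lists were progenitor, cell cycle, neurogenic, temporal, ganglion, horizontal, amacrine, cone, rod, shared photoreceptor, bipolar, Müller, astrocyte, microglia, endothelium, pericyte, red cell, pigment epithelium, lens, mesenchyme, muscle, myelin, synapse, cilium, glycolysis, oxidative phosphorylation, ribosomal protein, chromatin and immediate early genes.

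Genes were named by a rule. For each window these are the 8 largest rises and 8 largest falls among called genes with a mean of at least 20 CPM in the higher stage, both libraries of that stage above both of the other, and a symbol that is not a placeholder. For each list and window they are the 2 called members with the largest absolute change, and for each step the 2 largest rises and falls. In addition 29 genes were followed over all stages whatever their test. The comparisons, tests, lists, rule and the first set of alternatives were fixed before the data were examined. Genes outside the rule are said to have been chosen after their values were seen. Values of some genes that the rule or the lists take in, and tests that rest on them, are not reported here.

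Alternatives were DESeq2 1.42.0, RLE size factors, library size alone, no filter, a filter of 1 CPM in 4 libraries, a replicate block, leaving out each library in turn, fitting the compared stages only, no fold threshold, a test against a 2-fold change (glmTreat), and for lists an estimated inter-gene correlation and fry. Without a library, the lone library left in its stage was assumed to vary like those of other stages. Other alternatives were chosen after seeing the data. These were summed transcript estimates, protein-coding genes on the chromosomes only, removal of a GC trend per library, and comparisons that skip E12, P2 or P21. The protein-coding set had 16477 genes tested, and 126 of all tested genes lie on other scaffolds. The GC trend was a spline with 5 degrees of freedom, fitted on genes with a mean log2 CPM over 1. It was then applied to all 21616 genes with a GC value.

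The procedure was tested on simulated data with 100 genes changed per fold. All other genes were set equal in the compared stages. The noise was drawn independently per gene, with the variability estimated from these same data. Of genes changed 2-fold, 37% (E16 vs E11), 47% (P6 vs E16) and 46% (P28 vs P6) were called (65%, 73% and 71% passed the adjusted p alone), and of those changed 4-fold 95%, 94% and 94% were called. Of about 21580, 21590 and 21600 genes tested (rounded), 5, 8 and 7 unchanged genes were called. In the real windows 10014 to 10656 genes passed the adjusted p, far more than were changed here. These false calls therefore give no error rate for the real windows.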

Results

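Most genes measured in the 24 retina libraries changed with age. The leading principal component held 58% of the variance and the next 14.4%. Of 21858 genes tested, 16892 (77.3%) were called as differing between any of the 12 stages, and 19276 passed the adjusted p alone (edgeR quasi-likelihood F test with Benjamini-Hochberg). Of the called genes, 3694 (21.9%) had their highest mean at E11, 2235 (13.2%) at P21 and 2221 (13.1%) at P28, against 473 (2.8%) at P6. Among genes with a stage mean of at least 20 CPM, log2 values of replicates differed least at E16 (SD 0.19) and most at E11 (SD 0.438). Levels are given in TMM-scaled CPM, as mean ± SD over 2 libraries per stage unless single libraries are named.

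Cell cycle genes fell to a median of 1.05% of their peak at P28 and progenitor genes to 10.5%, from 48.5% and 62.6% at P2. Mki67, a marker of cycling cells, lay between 909 ± 100 (E11) and 1330 ± 99 CPM (P0) from E11 to P2, at 467 ± 22 at P4, 88.8 ± 16 at P6 and 0.0867 ± 0.041 at P28. Ccnd1, the cyclin of the G1 phase, stood at 575 ± 190 at E11, 3070 ± 210 at P0 and 17 ± 1.8 at P28. Fgf15, a growth factor of retinal progenitors, peaked at E14 with 1250 ± 160. Lin28b, a repressor of let-7 microRNAs, was highest at E11 (162 ± 70) and stood at 14.4 ± 2.2 at E16, while Nfix, a nuclear factor I gene, stood at 0.573 ± 0.16 at E11 and peaked at P2 with 83.2 ± 4.1. Across all 29 genes followed over the stages, adjusted p ran from 1.34e-18 (Slc17a7) to 0.000685 (Cryaa) in the edgeR quasi-likelihood F test with Benjamini-Hochberg.

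Markers of the retinal cell types peaked at different ages. Atoh7 and Pou4f2, transcription factors of ganglion cell formation, peaked at E14 (31.7 ± 3.9 and 152 ± 7.4). Otx2, needed for photoreceptor fate, peaked at P4 with 1080 ± 16, Neurod1 at P6 with 609 ± 7.8, and the photoreceptor regulator Crx at P10 with 1540 ± 88. The rod factors Nrl and Nr2e3 stood at 4.32 ± 0.062 and 0.396 ± 0.035 at E16 and at 920 ± 2 and 916 ± 1.5 at P6. Nr2e3 was highest at P10 (1020 ± 95) and Nrl at P28 (1350 ± 59).

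Cone, interneuron and glial markers peaked between P10 and P28. The short-wave cone opsin Opn1sw stood at 130 ± 30 at P0 and peaked at P21 (503 ± 45), whereas the middle-wave opsin Opn1mw had no counts up to E16, 0.928 ± 0.44 at P6 and 160 ± 26 at P28, when cone arrestin Arr3 reached 366 ± 54. The inhibitory amacrine gene Gad1 peaked at P21 (387 ± 4.7), the cholinergic gene Chat at P14 (14.9 ± 0.94) and the horizontal cell gene Lhx1 at P14 (12.9 ± 0.072). Grm6, the glutamate receptor of ON bipolar cells, peaked at P10 (232 ± 21), and Vsx1, a cone bipolar gene, at P14 (46.9 ± 0.15). The Müller glia gene Rlbp1 peaked at P14 (395 ± 7.7), Glul at P21 (2430 ± 40), the vesicular glutamate transporter Slc17a7 at P21 (1490 ± 9.9) and the pigment epithelium gene Rpe65 at P14 (10.7 ± 1.5).

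**Figure D1:**
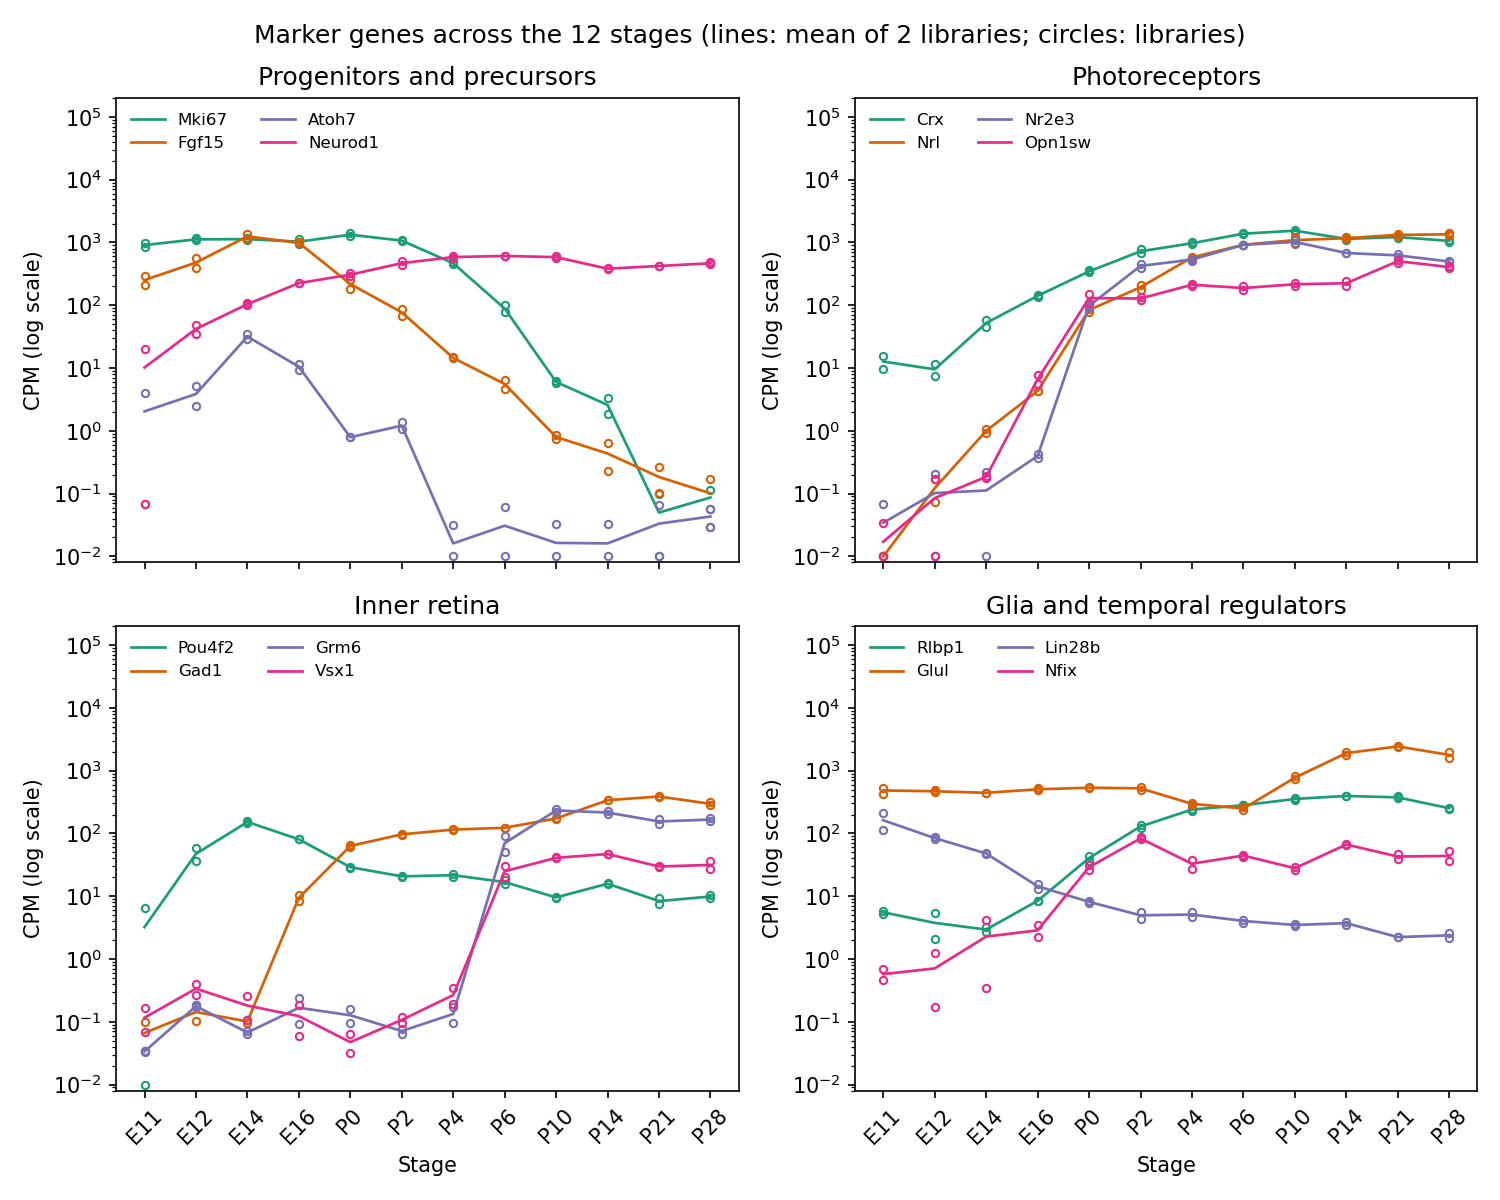
TMM CPM of 16 of the 29 genes followed over the 12 stages, with 1 point per library and lines through the stage means. Values of 0 are drawn at 0.01.

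The peak stages of whole gene lists are given as a description without a test. The stages with the most peaks are named, and all stages for ganglion cell genes. Of the members measured, 21 of 30 cell cycle genes, 40 of 42 ribosomal protein genes, 10 of 11 mesenchyme genes and 10 of 11 red cell genes were highest at E11. Ganglion cell genes peaked at E14 (7 of 20), E16 (7 of 20), P14 (5 of 20) and P10 (1 of 20). At P14 stood the peaks of 11 of 26 synapse, 8 of 23 bipolar, 6 of 15 Müller glia, 6 of 12 endothelium and 5 of 8 pericyte genes, and at P21 those of 11 of 16 rod, 13 of 28 shared photoreceptor and 11 of 21 glycolysis genes. Oxidative phosphorylation genes had peaks at E11 (17 of 41) and at P6 (13 of 41). Cone genes peaked most often at P28 (6 of 15) and P4 (3 of 15), and horizontal genes at P14 (4 of 9) and E14 (3 of 9). Amacrine peaks were spread out, with 5 of 20 at P14 and 3 of 20 each at P2 and P6.

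**Figure D2:**
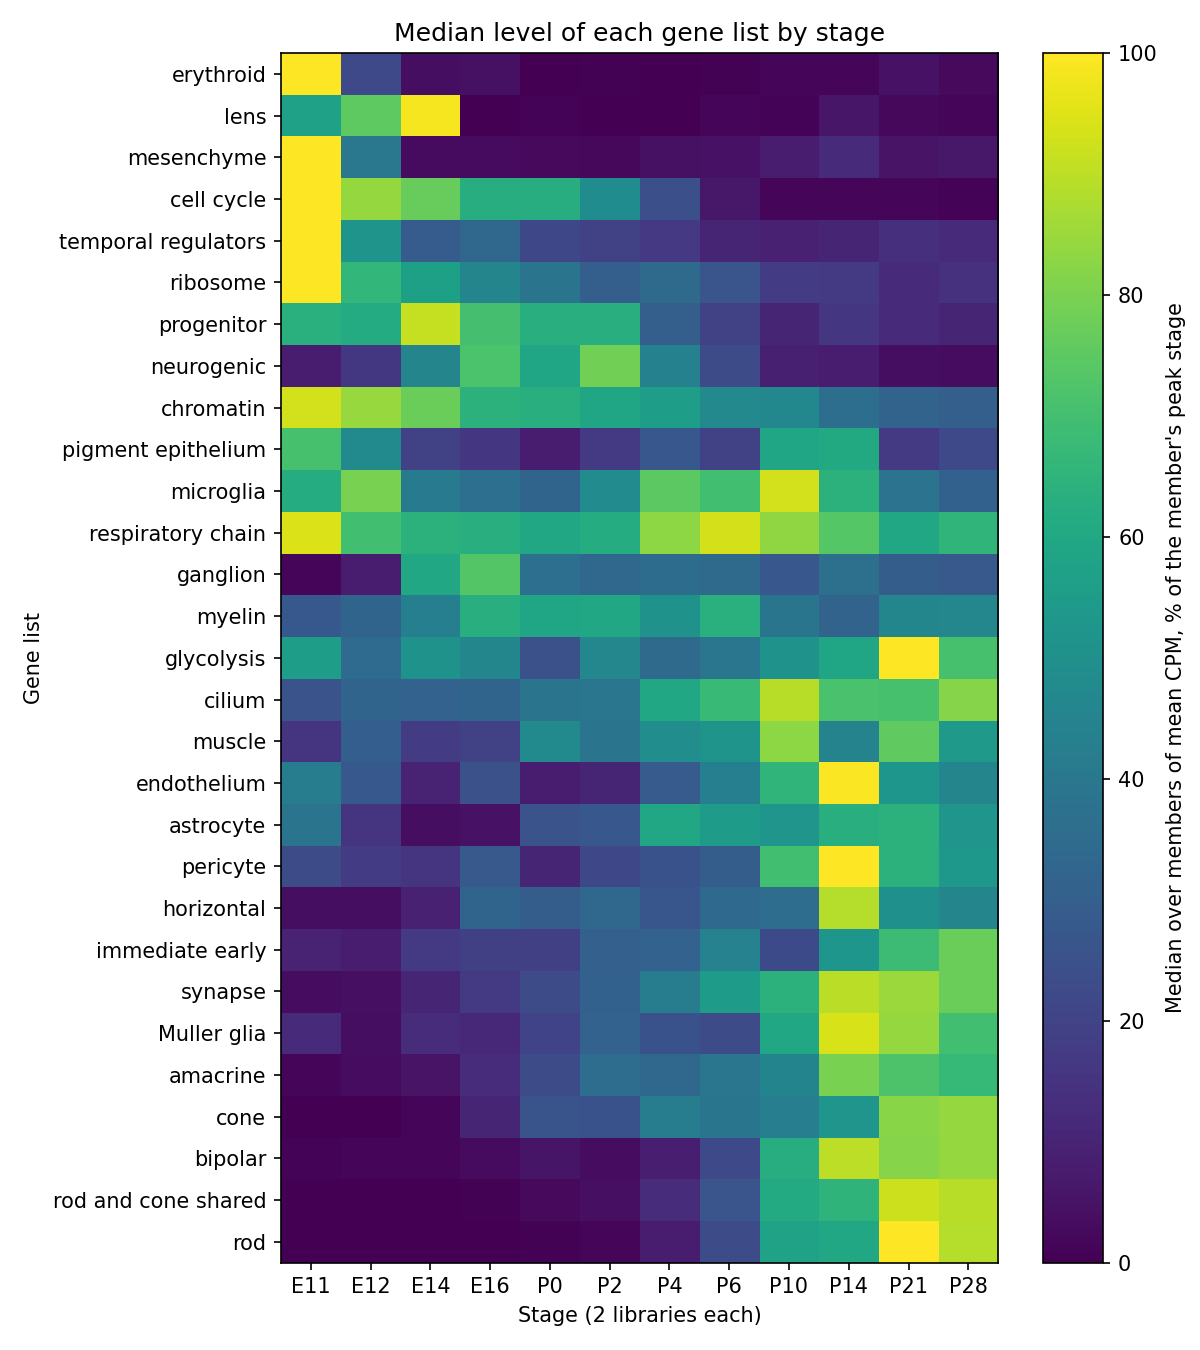
Median percent of each member's peak stage mean, for 29 gene lists over the 12 stages.

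From E11 to E16 most genes of the ganglion, amacrine, horizontal and cone lists rose. In this window 4958 genes were called, 2966 higher at E16 and 1992 lower (3401 and 1555 with library size alone, 4948 and 5066 with no fold threshold). Among the largest rises, the keratin Krt73 had no counts at E11 and 28.6 ± 0.717 CPM at E16, at least 568-fold higher. Thy1 and Pou4f3, both of ganglion cells, went from no counts to 9.82 ± 1.94 and 12.8 ± 0.463 (at least 195-fold and 253-fold), and Ptf1a, which directs amacrine and horizontal fates, to 10.8 ± 0.9 (at least 215-fold). The nicotinic receptor subunit Chrnb3, the homeobox gene Lhx4 and phosducin (Pdc) had 1 count each at E11 and stood at 43.4 ± 4.25, 27.1 ± 2.88 and 21.8 ± 0.482 at E16. Also near 0 at E11 were Mstn, the muscle growth inhibitor myostatin (53.7 ± 7.06 at E16), the amacrine factor Prdm13 (50.3 ± 9.19), the neurite outgrowth gene Nrn1 (36.1 ± 2.97) and the T-box gene Eomes (55 ± 0.334). Snap25, which drives vesicle fusion at synapses, rose from 1.02 ± 0.42 to 226 ± 6.82, a log2 change of 7.79 (SE 0.226, adjusted p = 2.22e-13, edgeR quasi-likelihood with Benjamini-Hochberg).

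The ganglion, neurogenic, horizontal, amacrine, cone, synapse and shared photoreceptor lists rose in this window. All 20 ganglion genes were called higher (median log2 change 5.24, camera adjusted p = 1.89e-43, Benjamini-Hochberg over the 87 list tests), as were 17 of 18 neurogenic genes (3.11, adjusted p = 2.77e-13). Neurod4 read 3.22 and 0.103 CPM in the E11 libraries and 214 ± 21.8 at E16, and Olig2 0.526 and 0.0343 against 23.2 ± 2.31. Of 9 horizontal genes 8 were higher, among them Slc32a1 and Lhx1 (median 3.26, adjusted p = 3.15e-08). Of 20 amacrine genes 12 were higher and 1 lower (1.93, or 1.97 with absent members at their bound, adjusted p = 2.27e-09), of 15 cone genes 12 higher (13 adjusted over the list alone; 3.33, or 3.5 at the bound, adjusted p = 3.86e-17), and of 26 synapse genes 21 (2.28, adjusted p = 5.09e-25). Pde6c, the cone phosphodiesterase, stood at 18.3 ± 0.571 and Opn1sw at 6.6 ± 1.47 at E16, with 1 count each at E11. The shared photoreceptor list had 14 of 28 higher and 3 lower (1.81, or 2.75 at the bound, adjusted p = 2.36e-07). With an estimated correlation, camera adjusted p was 0.000434 (ganglion), 0.0221 (neurogenic), 0.00326 (horizontal), 0.00367 (amacrine), 0.00121 (cone), 0.00114 (synapse) and 0.0349 (shared photoreceptor). Cdhr1, a photoreceptor cadherin, rose by 8.43 log2 units (SE 0.413), whereas Abca4 and Guca1b, singled out after their values were seen, were lower.

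Bipolar genes were split: 11 of 23 higher (12 adjusted over the list alone) and 3 lower, with a median of 1.3 (1.19 at the bound, camera adjusted p = 0.00232, and adjusted p = 0.0667 with an estimated correlation, range 4.19e-08 to 0.0667). Irx6 rose by 7.48 (SE 0.241), and Trpm1, a channel of ON bipolar cells and of pigment cells, singled out after its values were seen, went from 337 to 18.5 CPM. Rod genes did not pass as a list (6 of 16 higher, 1 lower, median 0.63, or 0.89 at the bound, adjusted p = 0.216, 0.00159 by fry, range 0.00159 to 0.696). Nrl was at least 85.7-fold higher, and Nr2e3 had 2 counts at E11 and read 0.396 ± 0.0354 at E16. Of 15 Müller genes 3 were higher, including the potassium channel Kcnj10 (0.23 and 0.549 at E11, 9.63 ± 1.02 at E16) and the receptor Gpr37 (4.34 and 2.09, 73.1 ± 1.06), and 4 lower. The median of that list was 0.06 (-0.15 at the bound), the mean 0.31 and the direction of the test down (adjusted p = 0.845).

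The progenitor list did not pass in camera (7 of 20 higher, 3 lower, median 0.30, camera adjusted p = 0.607, 0.00268 by fry, range 0.00268 to 0.808). Hes5, a Notch target, read 4.24 and 0.96 CPM at E11 and 55.7 ± 10 at E16, while cyclin Ccnd2 fell by 3.33 on the log2 scale (SE 0.816). Also lower were Sfrp2 and Id3, singled out after their values were seen. The temporal list, genes that mark early or late progenitors, had 7 of 14 lower and 3 higher (median -0.98, adjusted p = 0.006, and adjusted p = 0.127 with an estimated correlation, range 1.04e-05 to 0.127). Hmga2, a chromatin protein of early progenitors, fell by 3.89 (SE 0.17), and Lin28a read 48.8 and 222 CPM at E11 against 1.29 ± 0.629. The median of the 30 cell cycle genes was -0.68 with 6 lower and none higher (adjusted p = 1.04e-04, and adjusted p = 0.302 with an estimated correlation, range 1.65e-06 to 0.302). Its named members Rrm2 (-1.34, SE 0.17) and Tyms (-1.18, SE 0.132) had log2 changes of -0.99 and -0.90 without E11 replicate 2, under the 2-fold threshold, and summed transcript estimates gave Tyms -0.65.

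Ribosomal protein genes were lower in 32 of 42 (median -1.11, camera adjusted p = 2.77e-21, and adjusted p = 0.0759 with an estimated correlation, range 1.33e-22 to 0.0759), with Rplp1 (-1.85, SE 0.236) and Rps2 (-1.81, SE 0.153) moving most. None of 41 oxidative phosphorylation genes was called, with a median of -0.59 (adjusted p = 3.31e-06, and adjusted p = 0.469 with an estimated correlation, range 4.67e-08 to 0.469). Glycolysis genes had 3 of 21 higher and 3 lower (median direction down, adjusted p = 0.569, and 0.00873 without E11 replicate 1, range 0.00873 to 0.879), with the phosphofructokinase Pfkp up by 4.74 (SE 0.208) and the lactate transporter Slc16a1 down (-1.45, SE 0.154). Slc2a3, a glucose transporter singled out after its values were seen, changed sign without E11 replicate 2 (log2 change -1.18 with all libraries and 0.39 without), read -1.91 without E11 replicate 1, and lost its call without E16 replicate 1 or 2 (edgeR quasi-likelihood with Benjamini-Hochberg adjusted p = 0.0616 and 0.237, range 2.95e-05 to 0.366). Chromatin genes (1 higher, 1 lower of 15, adjusted p = 0.424, 0.0158 by fry, range 0.0158 to 0.616) held Dnmt3b, a DNA methyltransferase, down by -1.78 (SE 0.182). Cilium genes had 0 of 22 called (adjusted p = 0.818), and immediate early genes 2 of 12 higher, Arc among them (2.23, SE 0.524), and 1 lower (adjusted p = 0.639, 0.0171 by fry, range 0.0171 to 0.835).

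Lens genes differed by library as well as by stage. The 22 measured lens genes summed to 4230 CPM in E11 replicate 1 and 51.3 in replicate 2, and to 9.75 and 10.5 in the E16 libraries. Of them 15 were lower at E16 (17 adjusted over the list alone), with a median of -7.35 (-7.09 at the bound), camera adjusted p = 0.0272, adjusted p = 0.732 with an estimated correlation, 0.0664 by fry and 0.29 without E11 replicate 1, range 0.00024 to 0.732. The crystallin Cryaa, a structural protein of the lens, read 2080 and 3.5 CPM at E11 and had no counts at E16. Its call did not hold without E11 replicate 1 (adjusted p = 0.326) or E16 replicate 1 (0.0528), with a range of 7.94e-29 to 0.326 over 12 alternatives. Without E11 replicate 1 the calls of Cryge, Cryba1, Crybb3, Mip and Lim2 were lost too (adjusted p = 0.082, 0.867, 0.0565, 0.317 and 0.667, each the highest of its alternatives, whose lowest were 1.83e-04, 5.51e-07, 2.52e-08, 3.86e-04 and 0.00323). Those of Cryge, Cryba1, Mip and Lim2 were also lost without E16 replicate 1 (0.067, 0.0623, 0.0751 and 0.0933) and without E16 replicate 2 (0.0659, 0.0561, 0.0668 and 0.0869), edgeR quasi-likelihood with Benjamini-Hochberg throughout.

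Most red cell genes and all mesenchyme genes were lower at E16 than at E11. Of 11 red cell genes 9 were lower (median -4.46, camera adjusted p = 4.03e-05, and adjusted p = 0.128 with an estimated correlation, range 3.28e-09 to 0.128), and their sums were 3920 and 8670 CPM in the E11 libraries against 452 and 710 at E16. The embryonic globin Hbb-y fell by 11.68 (SE 0.575) from 2480 ± 813 CPM. Hba-x read 709 and 2350 at E11 against 0.289 ± 0.102, and Hbb-bh1 239 and 1710 against 1 count at E16, with adjusted p = 0.0575 by DESeq2 (range 4.3e-08 to 0.0575). The adult globin Hbb-bs, singled out after its values were seen, was higher at E16 (254 ± 81 against 63.1 ± 3.6), and its reads are uncertain between near-identical copies. All 11 mesenchyme genes were lower (median -4.83, camera adjusted p = 2.25e-06, and adjusted p = 0.0131 with an estimated correlation). Among them were Lum (29.6 and 9.23 against 0.0765 ± 0.023) and Twist1 (4.73 and 13.7 against 1 count at E16).

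Lists of other cell types did not pass in camera between E11 and E16. Several passed by fry, which does not compare a list with other genes. Pigment epithelium genes had 6 of 14 lower and 3 higher (median -0.58, camera adjusted p = 0.216, 0.0439 without E11 replicate 2, 0.0367 by fry, range 0.0367 to 0.696), with Mitf, the master regulator of pigment cells, down by -4.13 (SE 0.323) and Rgr at least 19.4-fold higher. Astrocyte genes had 2 of 5 lower (3 adjusted over the list alone), Pax2 (18.4 and 63.8 CPM against 1.81 ± 0.116) and Pdgfra (-2.61, SE 0.373), and 1 higher (adjusted p = 0.137, but 0.0169 without E11 replicate 1 and 0.0487 without replicate 2, 2.72e-05 by fry, range 2.72e-05 to 0.261). Microglia genes had 3 of 14 lower, with Tmem119 at -2.92 (SE 0.441) and Ptprc at -1.51 (SE 0.373) (adjusted p = 0.103, 0.00312 without E11 replicate 2, 0.00766 by fry, range 0.00312 to 0.617). For endothelium, 4 of 12 were lower, Emcn most (-2.59, SE 0.465), and 1 higher (adjusted p = 0.355), and for pericytes 2 of 8 were higher, Rgs5 (0.755 and 0.309 against 26.7 ± 7.61) and Kcnj8 (0.0336 ± 0.00103 against 0.823 ± 0.0271), and 1 lower (adjusted p = 0.577, 0.0171 by fry, range 0.0171 to 0.809). Myelin genes had 3 of 7 higher, Mbp by 2.34 (SE 0.205; adjusted p = 0.345, 1.32e-06 by fry, range 1.32e-06 to 0.469). Muscle genes had 1 of 5 higher and 1 lower (0 adjusted over the list alone; adjusted p = 0.849). For the other lists of this window, counts adjusted over the list alone equalled those over all genes.

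Other called members of lists with few calls in this window, singled out after their values were seen, were rod Reep6 (-1.29, SE 0.163), bipolar Car8 (-1.25, SE 0.187), Müller Slc1a3 (1.60, SE 0.193), Car14 (-3.17, SE 0.129) and Apoe (-1.95, SE 0.181), endothelium Egfl7 (-1.46, SE 0.319), myelin Cnp (1.37, SE 0.147), glycolysis Eno2 (1.19, SE 0.158) and Hk1 (1.36, SE 0.111) (edgeR log2 changes).

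Many calls in short lists from E11 to E16 were lost, or their log2 changes moved, when 1 library was left out. Such a fit leaves 1 library in the stage, so a lost call can come from the smaller sample alone. A lost call with a similar log2 change therefore does not show that the call rested on that library. Slco1c1, Myh3, Tnni2, Mog and Npas4 come from the naming rule and the other genes were singled out after their values were seen. A p is edgeR quasi-likelihood with Benjamini-Hochberg, with its range over the alternatives. Temporal Casz1 (1.21, SE 0.213) read 0.80 without E11 replicate 2, below the threshold, and 1.82 without E11 replicate 1. Temporal Nfia (2.75, SE 0.326) read 3.56 without E11 replicate 1. Temporal Nfix (2.32, SE 0.744) was not called without E11 replicate 1 (adjusted p = 0.0917), E11 replicate 2 (adjusted p = 0.0569) or E16 replicate 1 (adjusted p = 0.108), range 8.46e-06 to 0.108. Amacrine Th (-1.02, SE 0.401) was not called without E11 replicate 1 (adjusted p = 0.0855), E11 replicate 2 (adjusted p = 0.142) or E16 replicate 2 (adjusted p = 0.388), range 0.00749 to 0.388, and read -1.82 without E16 replicate 1. Shared photoreceptor Guca1a (-2.70, SE 0.568) read -3.60 without E16 replicate 1. Bipolar Scgn (-2.40, SE 0.862) was not called without E11 replicate 1 (adjusted p = 0.273), E16 replicate 1 (adjusted p = 0.0962) or E16 replicate 2 (adjusted p = 0.134), range 0.00162 to 0.273, and read -1.60 without E11 replicate 1. Müller Clu (-1.55, SE 0.384) was not called without E11 replicate 1 (adjusted p = 0.0757), range 0.000659 to 0.0757, and read -0.93 without E11 replicate 1. Müller Vim (-1.09, SE 0.161) read -0.68 without E11 replicate 1, below the threshold. Astrocyte S100b (2.36, SE 0.729) was not called without E11 replicate 2 (adjusted p = 0.143) or E16 replicate 1 (adjusted p = 0.0639), range 0.00197 to 0.143, and read 1.44 without E11 replicate 2 and 6.1 without E11 replicate 1. Microglia C1qb (-1.10, SE 0.276) was not called without E11 replicate 1 (adjusted p = 0.166), range 3.17e-05 to 0.166, and read -0.99 without E16 replicate 1, below the threshold, and -0.42 without E11 replicate 1. Endothelium Tek (-2.35, SE 0.473) read -2.93 without E11 replicate 1 and -1.34 without E11 replicate 2. Endothelium Esam (-1.08, SE 0.393) was not called without E11 replicate 2 (adjusted p = 0.326), E16 replicate 1 (adjusted p = 0.136) or E16 replicate 2 (adjusted p = 0.106), range 0.011 to 0.326. Endothelium Slco1c1 (3.66, SE 0.913) read 6.02 without E11 replicate 1 and 2.84 without E11 replicate 2. Pericyte Des (-2.02, SE 0.55) was not called without E16 replicate 2 (adjusted p = 0.084), range 0.000699 to 0.084, and read -2.98 without E16 replicate 1. Pigment epithelium Lrat (2.12, SE 0.644) was not called without E11 replicate 2 (adjusted p = 0.0766), range 0.00832 to 0.0766. Pigment epithelium Ttr (2.97, SE 0.763) was not called without E11 replicate 2 (adjusted p = 0.0668), range 2.94e-05 to 0.0668, and read 2.22 without E11 replicate 2 and 4.83 without E11 replicate 1. Muscle Myh3 (1.96, SE 0.655) was not called without E11 replicate 2 (adjusted p = 0.118) or E16 replicate 1 (adjusted p = 0.132), range 3.47e-05 to 0.182, and read 1.00 without E11 replicate 2 and 7.62 without E11 replicate 1. Muscle Tnni2 (-2.28, SE 0.86) was not called without E11 replicate 1 (adjusted p = 0.0954), E11 replicate 2 (adjusted p = 0.149), E16 replicate 1 (adjusted p = 0.146) or E16 replicate 2 (adjusted p = 0.208), range 0.034 to 0.262. Myelin Mog (1.83, SE 0.603) was not called without E11 replicate 2 (adjusted p = 0.143) or E16 replicate 1 (adjusted p = 0.133), range 0.0133 to 0.143. Glycolysis Ldhb (-1.11, SE 0.163) read -0.65 without E11 replicate 2, below the threshold. Immediate early Ier2 (-1.06, SE 0.309) was not called without E11 replicate 2 (adjusted p = 0.41) or E16 replicate 1 (adjusted p = 0.0572), range 0.000126 to 0.41, and read -0.32 without E11 replicate 2. Leaving out any library did not end the call of immediate early Npas4 (4.77, SE 0.423).

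RNA input changed with stage here, since 100 ng went into the E11 and E12 libraries and 1 µg into the rest. The steps with equal input called 1749 genes (E12 vs E11) and 1559 (E16 vs E14), against 2382 where the input changed (E14 vs E12). The count of E12 vs E11 varied widely with the libraries and stages fitted, as given below, so these counts do not separate input from stage. Scaling by library size alone shifted the median log2 change of all genes in E16 vs E11 by 0.14.

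Between E16 and P6 cell cycle genes fell and rod genes rose. Here 5451 genes were called, 2888 higher at P6 and 2563 lower (2948 and 2474 with library size alone, 4985 and 5309 with no fold threshold). Nr2e3 rose from 0.396 ± 0.0354 to 916 ± 1.47 CPM (log2 change 11.16, SE 0.33). The rod channel and phosphodiesterase genes Cnga1 and Pde6b had 1 and 3 counts at E16 and stood at 534 ± 32.2 and 873 ± 75 at P6. Recoverin (Rcvrn), the paired box gene Pax7 and the peptide receptor Glp2r had 1 count each at E16 and stood at 74.7 ± 1.87, 30.7 ± 1.93 and 28 ± 4, and Samd7 went from 0.541 and 0.247 to 435 ± 37.7. Among the largest falls were Fgf15 (log2 change -7.47, SE 0.314), the progenitor factor Foxn4 (-6.07, SE 0.753), the repair nuclease Exo1 (-5.85, SE 0.359), the hedgehog effector Gli1 (-5.66, SE 0.569) and the retinoic acid binding protein Crabp2 (-5.53, SE 0.171). Dio3, a thyroid hormone deiodinase, went from 21.4 ± 1.97 to 0.0953 and 0.216, Ecel1 from 23.9 ± 6.13 to 0.477 and 0.216, and Krt73 from 28.6 ± 0.717 to 0.254 and 0.647.

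All 16 rod genes and all 28 shared photoreceptor genes rose, with median log2 changes of 8.56 and 4.89 (camera adjusted p = 1.86e-107 and 2.49e-90, Benjamini-Hochberg). Their estimated correlations were 0.263 and 0.0942, and with these camera gave adjusted p = 6.83e-06 and 3.38e-06. Of 15 cone genes 11 were higher (median 1.61, adjusted p = 1.38e-11), cone arrestin Arr3 by 7.71 (SE 0.319) and Opn1mw at least 20.3-fold, and 1 was lower, the thyroid hormone receptor Thrb, singled out after its values were seen. Bipolar genes were higher in 16 of 23 and lower in none (median 2.1, adjusted p = 8.58e-13), with Sebox at least 50-fold higher and Grm6 at 0.241 and 0.0928 CPM at E16 and 89.9 and 50.2 at P6. Amacrine genes had 11 of 20 higher and 2 lower (median 1.24, adjusted p = 3.31e-06), neuropeptide Y (Npy) by 5.94 (SE 0.199) and Vip at least 17.1-fold. Synapse genes were higher in 16 of 26 (1.56, adjusted p = 3.86e-17), led by Slc17a7 (7.31, SE 0.182) and Cplx4 (5.87, SE 0.163), a complexin of photoreceptor synapses. Cilium genes were higher in 11 of 22 (1.00, adjusted p = 2.44e-07, and adjusted p = 0.0617 with an estimated correlation, range 2.55e-08 to 0.0617), with Arl6 at 2.64 (SE 0.105) and Cep290 at 2.49 (SE 0.161). Müller genes were higher in 7 of 15 and lower in 2 (0.94, adjusted p = 0.00263), Rlbp1 by 5.06 (SE 0.239). At the estimated correlation, camera adjusted p was 0.0036 (cone), 0.0012 (bipolar), 0.00919 (amacrine), 0.00326 (synapse) and 0.0349 (Müller).

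Every one of the 30 cell cycle genes fell (median -3.33, camera adjusted p = 1.53e-62), such as the replication helicase gene Mcm3 (-4.21, SE 0.208) and the mitotic kinase Plk1 (-4.16, SE 0.289). Progenitor genes fell in 16 of 20 (median -1.70, adjusted p = 8.92e-15), with Sfrp2 at -4.83 (SE 0.173). Neurogenic genes were lower in 10 of 18 (11 adjusted over the list alone) and higher in 3 (median -1.58, adjusted p = 0.00244, and adjusted p = 0.374 with an estimated correlation, range 0.000159 to 0.374), and Atoh7 read 10.5 ± 1.82 at E16 against 2 counts at P6. Of 14 temporal genes 8 were lower, Igf2bp1 by -4.53 (SE 0.257), and 1 was higher, Nfix by 3.95 (SE 0.54), with a median of -1.70 (adjusted p = 0.00162, and adjusted p = 0.0678 with an estimated correlation, range 1.95e-07 to 0.0678). Ganglion genes had 12 of 20 lower (median -1.30), while Nefh (3.17, SE 0.219) and Thy1 (3.04, SE 0.135) rose. For this list camera gave adjusted p = 0.0522, and 0.0496 both with RLE size factors and with a replicate block. By fry it was 0.000531, and the range was 0.000531 to 0.498. Horizontal genes had 3 of 9 higher, Sept4 by 2.44 (SE 0.108), and 3 lower, the Onecut factors (Onecut1 -2.49, SE 0.498; adjusted p = 0.137 for the list, 6.36e-05 by fry, range 6.36e-05 to 0.352). Chromatin genes fell in 6 of 15 (-0.45, adjusted p = 1.67e-04), among them Uhrf1 (-4.97, SE 0.23), which keeps DNA methylation through replication, and Hmgb2 (-2.39, SE 0.124). Under an estimated correlation, camera adjusted p was 0.000434 (cell cycle), 0.000453 (progenitor) and 0.0157 (chromatin).

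Ribosomal protein genes were lower in 11 of 42 (median -0.77, camera adjusted p = 1.59e-07, and adjusted p = 0.368 with an estimated correlation, range 3.01e-08 to 0.368), Rplp2 by -1.48 (SE 0.255) and Rpl14 by -1.37 (SE 0.209). Oxidative phosphorylation genes were higher in 6 of 41 (0.52, adjusted p = 9.48e-05, and adjusted p = 0.551 with an estimated correlation, range 1.68e-05 to 0.551), among them Ndufa5 (1.09, SE 0.148) and Cox8a (1.08, SE 0.148). The share of counts on mitochondrial genes was 3.06% and 3.53% at E16, 6.14% and 6.11% at P4 and 6.09% and 5.79% at P6. Glycolysis genes had 3 of 21 higher, with the aldolase Aldoc at 4.44 (SE 0.265) and the neuronal enolase Eno2 at 2.81 (SE 0.157), and 4 lower (adjusted p = 0.537). Immediate early genes were higher in 6 of 12 (7 adjusted over the list alone; adjusted p = 0.174, 0.000261 by fry, range 0.000261 to 0.525), Egr1 by 5.53 (SE 0.641).

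In camera the astrocyte and red cell lists passed from E16 to P6, and the microglia, endothelium, pericyte, pigment epithelium, muscle and mesenchyme lists did not. Astrocyte genes were higher in 3 of 5 (median 3.72, camera adjusted p = 0.0146, and adjusted p = 0.0586 with an estimated correlation, range 2.18e-08 to 0.0586), Pdgfra by 3.80 (SE 0.386) and S100b by 4.13 (SE 0.426). Microglia genes had 5 of 14 higher, Ctss by 1.46 (SE 0.218) (adjusted p = 0.103, 0.0438 without E16 replicate 2, 0.0012 by fry, range 0.0012 to 0.617), endothelium 4 of 12, Tek by 2.45 (SE 0.473) (adjusted p = 0.171, 0.0111 by fry, range 0.0111 to 0.696), and pericytes 1 higher, Rgs5 (1.80, SE 0.33), and 1 lower, Pdgfrb (-1.32, SE 0.204), of 8 (adjusted p = 0.751). Pigment epithelium genes had 4 of 14 higher, Ttr by 3.74 (SE 0.451), and 1 lower (adjusted p = 0.345, 0.0279 by fry, range 0.0279 to 0.778). Red cell genes were lower in 7 of 11 (median -4.30, or -4.14 at the bound, adjusted p = 0.00394, and adjusted p = 0.31 with an estimated correlation, range 2.19e-05 to 0.31). Hbb-y had no counts at P6 and 0.511 and 0.989 CPM at E16, a call lost without E16 replicate 2 (0.0591) or P6 replicate 1 (0.0514) (range 6.2e-05 to 0.0591). Muscle genes were higher in 3 of 5, Myh8 by 1.83 (SE 0.389) (adjusted p = 0.397, 0.000183 by fry, range 0.000183 to 0.525), and mesenchyme genes gave 1 higher, Postn (2.91, SE 0.582), and 1 lower, Col1a2 (-1.62, SE 0.325), of 11 (adjusted p = 0.82).

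Of 7 myelin genes 1 was lower, Cldn11 (1.81 ± 0.0568 against 0.191 and 0.555), and the list's median was 0.07, its mean -0.04 and its test up (camera adjusted p = 0.842). Lens genes had 2 of 22 higher, Cryab and Lgsn, and 0 adjusted over the list alone (median 3.78, or 2.64 at the bound, adjusted p = 0.405). Lgsn had 8 counts at P6 and none at E16, and its call was lost without E16 replicate 1 (0.0596), E16 replicate 2 (0.0595) or P6 replicate 1 (0.0601), with a range of 0.0119 to 0.0601. Cryab (1.19 ± 0.282 to 9.88 ± 0.8) lost its call without any 1 of the 4 libraries (0.183 and 0.138 for E16 replicates 1 and 2, 0.0835 and 0.103 for those of P6, edgeR quasi-likelihood with Benjamini-Hochberg, range 2.96e-05 to 0.183). For the other lists of this window, counts adjusted over the list alone equalled those over all genes.

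Further called members of short counts from E16 to P6, singled out after their values were seen, were neurogenic Otx2 (1.97, SE 0.234), horizontal Slc32a1 (1.46, SE 0.205), Calb1 (2.40, SE 0.345), Onecut2 (-1.53, SE 0.316) and Onecut3 (-1.39, SE 0.309), amacrine Gad2 (-1.40, SE 0.227), pigment epithelium Rgr (2.85, SE 0.406), glycolysis Hk1 (1.33, SE 0.109), Slc2a1 (-1.59, SE 0.139) and Slc16a3 (-1.56, SE 0.285) (edgeR log2 changes).

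Leaving out 1 library also ended calls or moved log2 changes in short lists from E16 to P6, and the smaller sample alone can end a call. Fcrls, Rpe65, Acta1 and Slco1c1 come from the naming rule, and the other genes were singled out after their values were seen. Each p is from edgeR quasi-likelihood with Benjamini-Hochberg, with the range over the alternatives. Neurogenic Neurod4 (1.36, SE 0.383) was not called without E16 replicate 1 (adjusted p = 0.0647), range 4e-05 to 0.0962. Neurogenic Insm1 (1.40, SE 0.416) was not called without E16 replicate 1 (adjusted p = 0.0621) or E16 replicate 2 (adjusted p = 0.0552), range 8.76e-06 to 0.0621. Müller Glul (-1.02, SE 0.112) read -0.97 without E16 replicate 2 and -0.95 without P6 replicate 1, below the threshold. Astrocyte Gfap (3.72, SE 0.514) read 5.35 without E16 replicate 1 and 2.97 without E16 replicate 2. Microglia Tyrobp (1.14, SE 0.328) was not called without E16 replicate 1 (adjusted p = 0.0935) or P6 replicate 2 (adjusted p = 0.0575), range 0.0064 to 0.0935. Microglia Trem2 (1.18, SE 0.436) was not called without E16 replicate 1 (adjusted p = 0.234), P6 replicate 1 (adjusted p = 0.0685) or P6 replicate 2 (adjusted p = 0.123), range 0.0141 to 0.234. Microglia Fcrls (1.26, SE 0.363) was not called without E16 replicate 1 (adjusted p = 0.0874), range 0.00171 to 0.0874. Endothelium Pecam1 (1.11, SE 0.224) read 0.97 without E16 replicate 1, below the threshold. Endothelium Esam (1.39, SE 0.392) was not called without E16 replicate 1 (adjusted p = 0.0509), range 0.000573 to 0.0509. Pigment epithelium Rpe65 (4.36, SE 0.917) read 7.96 without E16 replicate 1 and 3.43 without E16 replicate 2. Pigment epithelium Dct (1.57, SE 0.411) was not called without E16 replicate 1 (adjusted p = 0.0727), range 0.000259 to 0.0727. Pigment epithelium Best1 (-1.89, SE 0.587) was not called without E16 replicate 2 (adjusted p = 0.104) or P6 replicate 1 (adjusted p = 0.109), range 0.000485 to 0.109. Muscle Acta1 (1.48, SE 0.458) was not called without E16 replicate 2 (adjusted p = 0.0852) or P6 replicate 2 (adjusted p = 0.0762), range 0.00983 to 0.0852. Muscle Myh3 (1.35, SE 0.526) was not called without E16 replicate 1 (adjusted p = 0.0708), E16 replicate 2 (adjusted p = 0.24), P6 replicate 1 (adjusted p = 0.113) or P6 replicate 2 (adjusted p = 0.11), range 0.00892 to 0.24. Glycolysis Hk2 (-1.01, SE 0.259) was not called without P6 replicate 2 (adjusted p = 0.0692), range 0.000343 to 0.0692, and read -0.98 without E16 replicate 2, below the threshold. Glycolysis Slc16a1 (-1.07, SE 0.156) read -0.93 without E16 replicate 2, below the threshold. Leaving out any library did not end the call of amacrine Ptf1a (-5.50, SE 0.522), Müller Vim (-1.02, SE 0.161), microglia C1qb (1.26, SE 0.276) and endothelium Slco1c1 (3.48, SE 0.429).

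From P6 to P28 most genes of the rod, shared photoreceptor and bipolar lists rose. In this window 5403 genes were called, 3111 higher at P28 and 2292 lower (2738 and 2622 with library size alone, 5285 and 5371 with no fold threshold). The rod transducin Gnat1 rose from 33.3 ± 0.725 to 6220 ± 213 CPM (log2 change 7.54, SE 0.334, adjusted p = 1.89e-11, edgeR quasi-likelihood with Benjamini-Hochberg), the cyclase activator Guca1b from 4.81 ± 1.04 to 1050 ± 115 (7.77, SE 0.192), the potassium channel Kcnj14 from 1.24 ± 0.138 to 425 and 465 (8.49, SE 0.175) and Opn1mw from 0.928 ± 0.441 to 160 ± 25.5 (7.43, SE 0.302). The dopamine receptor Drd4 (8.10, SE 0.302), Pdzph1 (7.70, SE 0.437) and the nesprin Syne3 (7.39, SE 0.28) rose as much, and Folh1 went from 3 counts to 31 ± 7.94. Tmem92 had 55.7 ± 5.03 CPM at P6 and no counts at P28, at least 1290-fold lower, and the transcript AA623943 was at least 469-fold lower. Falls were also large for Mki67 (-9.94, SE 0.339), the progenitor and glial lipid binding protein Fabp7 (-8.21, SE 0.257), Mfap4 (-6.46, SE 0.303) and Insm2 (-6.34, SE 0.591). Pax7 went from 30.7 ± 1.93 to 2 counts, and the imprinted RNA H19 from 59.4 ± 13.5 to 0.172 and 0.957.

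Rod genes were higher in 12 of 16 and lower in 1 (median 2.12, camera adjusted p = 3.15e-27, Benjamini-Hochberg), with the exchanger Slc24a1 at 6.80 (SE 0.117), and shared photoreceptor genes were higher in 19 of 28 (1.90, adjusted p = 1.16e-27). The shared list also holds Cabp4 (4.15, SE 0.156), whose reads are uncertain because the annotation carries a duplicate copy. Bipolar genes were higher in 18 of 23 and lower in 1 (1.84, adjusted p = 5.13e-13), Gng13 by 5.32 (SE 0.351) and Pcp2 by 4.98 (SE 0.342), both of bipolar cells that answer to light onset. Müller genes were higher in 6 of 15 and lower in 1 (0.83, adjusted p = 3.1e-05), including the water channel Aqp4 (6.34, SE 0.323) and Abca8a (5.87, SE 0.444). Cone genes were higher in 8 of 15, Arr3 by 3.35 (SE 0.194), and lower in 2 (1.11, adjusted p = 3.83e-04, and adjusted p = 0.0759 with an estimated correlation, range 9.4e-07 to 0.0759). Synapse genes were higher in 6 of 26 and lower in 3 (0.48, adjusted p = 0.00705, and adjusted p = 0.302 with an estimated correlation, range 4.6e-05 to 0.302), Cplx4 from 51.8 ± 3.53 to 454 ± 14.8 CPM and Slc17a7 by 2.23 (SE 0.134). Glycolysis genes were higher in 7 of 21 (0.68, adjusted p = 6.6e-06, and adjusted p = 0.267 with an estimated correlation, range 6.27e-07 to 0.267), with hexokinase Hk2 at 3.79 (SE 0.281) and Slc16a1 at 3.14 (SE 0.164).

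Cell cycle genes fell further, in 20 of 30 (median -2.51, camera adjusted p = 2.71e-33), Cdk1 by -5.65 (SE 0.217). Neurogenic genes were lower in 15 of 18 and higher in none (-2.78, or -3.01 at the bound, adjusted p = 2.71e-12), with Olig2 at least 88.0-fold and Foxn4 at least 48.0-fold lower. Progenitor genes were lower in 8 of 20 (-0.88, adjusted p = 8.25e-05), Ccnd1 by -3.73 (SE 0.232), with Fgf15 at 5.57 ± 1.4 CPM at P6 and 0.172 and 0.029 at P28. Chromatin genes were lower in 5 of 15 (-0.57, adjusted p = 0.0011), the histone variant H2afz by -1.76 (SE 0.168) and Uhrf1 from 8.24 ± 1.9 to 0.603 and 0.203 CPM. Ribosomal protein genes were lower in 26 of 42 (-1.06, adjusted p = 7.58e-18, and adjusted p = 0.108 with an estimated correlation, range 1.44e-20 to 0.108), Rpl10 by -2.54 (SE 0.227) and Rpl27 by -2.19 (SE 0.266). Oxidative phosphorylation genes had 3 of 41 lower, among them Atp5o (-1.30, SE 0.114) and Ndufa1 (-1.29, SE 0.172), and a median of -0.49 (adjusted p = 1.71e-04, and adjusted p = 0.56 with an estimated correlation, range 1.48e-05 to 0.56).

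The amacrine, ganglion, horizontal, temporal, immediate early and cilium lists did not pass in camera from P6 to P28. Amacrine genes had 7 of 20 higher, Vip by 4.09 (SE 0.4), and 3 lower (camera adjusted p = 0.0936, 0.036 without P28 replicate 2, 4.89e-05 by fry, range 4.89e-05 to 0.334). Ptf1a had 1 count at P28, and its call was lost without P28 replicate 1 (edgeR quasi-likelihood with Benjamini-Hochberg adjusted p = 0.0669, range 0.00669 to 0.0669). Ganglion genes had 5 of 20 lower, the growth cone gene Gap43 by -2.34 (SE 0.172), and 2 higher, the neurofilament Nefh by 2.07 (SE 0.19) (adjusted p = 0.482). Horizontal genes had 2 of 9 higher, the calcium buffer Calb1 by 2.31 (SE 0.315), and 1 lower, Onecut2 by -1.83 (SE 0.327) (adjusted p = 0.812). Temporal genes gave 1 of 14 higher (2 adjusted over the list alone) and 2 lower, Igf2bp1 (-1.52, SE 0.28) and Nfib (-1.30, SE 0.199) (adjusted p = 0.752). Immediate early genes had 4 of 12 higher, Junb by 2.74 (SE 0.381), and 1 lower, Egr2, with 2 counts at P28 (adjusted p = 0.216, 0.00117 by fry, range 0.00117 to 0.551). Cilium genes were higher in 3 of 22, Kif17 by 2.08 (SE 0.351) and Arl13b by 1.10 (SE 0.172; 0.99 without P28 replicate 1), with a median of -0.00047, a mean of 0.22 and a test up (adjusted p = 0.424, 0.0431 by fry, range 0.0431 to 0.808).

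Microglia genes were lower in 7 of 14 (8 adjusted over the list alone) and higher in 1 (median -1.04, camera adjusted p = 0.0348, adjusted p = 0.53 with an estimated correlation, 0.0605 with library size alone and 0.0516 without P6 replicate 2, range 0.000383 to 0.53), Fcrls by -2.61 (SE 0.39) and Tyrobp by -1.83 (SE 0.34). Astrocyte genes had 2 of 5 lower, Pdgfra (-2.72, SE 0.362) and Pax2 (-2.08, SE 0.424), and 1 higher (adjusted p = 0.751). Endothelium genes had 3 of 12 higher, the receptor Flt1 by 2.30 (SE 0.342), and 1 lower, with a median of -0.28, a mean of 0.20 and a test up (adjusted p = 0.552). Pericyte genes had 1 of 8 higher, Des (0.438 ± 0.0346 to 1.31 ± 0.234, adjusted p = 0.487 for the list, 0.0357 by fry, range 0.0357 to 0.763). The call of Des was lost without P6 replicate 1 (0.113), P6 replicate 2 (0.0844) or P28 replicate 2 (0.108), and with summed transcript estimates (0.0954), edgeR quasi-likelihood with Benjamini-Hochberg, range 0.0079 to 0.113. Pigment epithelium genes had 4 of 14 higher, Lrat among them (0.318 and 0.678 to 4.68 ± 0.972), and 3 lower, the melanosome gene Pmel among them (15.9 ± 6.4 to 0.89 and 3.54; adjusted p = 0.818). Red cell genes were higher in 5 of 11 (3 adjusted over the list alone; adjusted p = 0.474), Hba-a1 by 2.39 (SE 0.49) and Hba-a2 by 1.71 (SE 0.395), near-identical genes whose reads are uncertain between the copies.

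The remaining lists of P28 vs P6 had few members called. Myelin genes had 1 of 7 lower, Cnp by -1.34 (SE 0.141; camera adjusted p = 0.474, 6.84e-05 by fry, range 6.84e-05 to 0.578). Muscle genes had 1 of 5 lower, Myh3 (2.02 ± 0.0224 to 0.115 and 0.029), with a median of 0.28, a mean of -0.49 and a test down (adjusted p = 0.608, 0.00984 by fry, range 0.00984 to 0.822). None of 22 lens and 11 mesenchyme genes was called by edgeR quasi-likelihood, with medians of -0.31 and 0.32, tests up for both (adjusted p = 0.841 and 0.818) and a mean of -0.16 for mesenchyme. For the other lists of this window, counts adjusted over the list alone equalled those over all genes.

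Among lists with few calls from P6 to P28, members singled out after their values were seen were ganglion Stmn2 (-1.88, SE 0.498), Eomes (-1.63, SE 0.229), Tubb3 (-1.37, SE 0.286) and Ebf3 (-1.20, SE 0.191), horizontal Slc32a1 (1.3, SE 0.196), amacrine Npy (-2.33, SE 0.156), cone Gngt2 (-1.82, SE 0.194), bipolar Irx5 (-1.87, SE 0.377), astrocyte Aldh1l1 (1.98, SE 0.444), synapse Cplx2 (-1.55, SE 0.129) and Nlgn1 (-1.46, SE 0.267), chromatin Ezh2 (-1.74, SE 0.194), Hmgb2 (-1.60, SE 0.123) and Hdac2 (-1.28, SE 0.117), immediate early Fos (2.28, SE 0.304), Fosb (2.36, SE 0.454) and Npas4 (2.03, SE 0.272) (edgeR log2 changes).

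From P6 to P28 calls in short lists were likewise lost or moved without 1 library, and again the smaller sample alone can end a call. Slco1c1 comes from the naming rule, and the other genes were singled out after their values were seen. Each p is from edgeR quasi-likelihood with Benjamini-Hochberg, with the range over the alternatives. Temporal Pou2f2 (1.13, SE 0.271) was not called without P28 replicate 1 (adjusted p = 0.0705), range 9.42e-05 to 0.0849, and read 0.94 without P6 replicate 1, below the threshold. Ganglion Rbfox3 (1.06, SE 0.382) was not called without P6 replicate 1 (adjusted p = 0.0903), P6 replicate 2 (adjusted p = 0.145) or P28 replicate 1 (adjusted p = 0.19), range 0.00201 to 0.19. Amacrine Nr4a2 (-2.12, SE 0.758) was not called without P6 replicate 1 (adjusted p = 0.0863), P6 replicate 2 (adjusted p = 0.0566) or P28 replicate 2 (adjusted p = 0.184), range 0.000956 to 0.184, and read -2.77 without P28 replicate 1. Cone Rxrg (-1.17, SE 0.266) read -0.93 without P6 replicate 2, below the threshold. Rod Samd7 (-1.14, SE 0.191) read -0.91 without P28 replicate 2, below the threshold. Müller Vim (-1.11, SE 0.162) read -0.94 without P28 replicate 2, below the threshold. Microglia Tmem119 (1.59, SE 0.484) was not called without P6 replicate 1 (adjusted p = 0.112), range 0.00246 to 0.112. Endothelium Esam (1.15, SE 0.372) was not called without P6 replicate 1 (adjusted p = 0.0667), P6 replicate 2 (adjusted p = 0.101) or P28 replicate 1 (adjusted p = 0.0996), range 0.000679 to 0.101. Endothelium Egfl7 (-1.05, SE 0.323) was not called without P6 replicate 2 (adjusted p = 0.0631) or P28 replicate 2 (adjusted p = 0.0831), range 0.00211 to 0.3. Red cell Hbb-bs (1.17, SE 0.394) was not called without P6 replicate 1 (adjusted p = 0.0912), P6 replicate 2 (adjusted p = 0.0936) or P28 replicate 1 (adjusted p = 0.1), range 0.000183 to 0.1. Red cell Hbb-bt (1.31, SE 0.52) was not called without P6 replicate 1 (adjusted p = 0.214), P6 replicate 2 (adjusted p = 0.0955), P28 replicate 1 (adjusted p = 0.186) or P28 replicate 2 (adjusted p = 0.0679), range 0.00357 to 0.214. Red cell Epb42 (1.13, SE 0.454) was not called without P6 replicate 1 (adjusted p = 0.0851), P6 replicate 2 (adjusted p = 0.235) or P28 replicate 1 (adjusted p = 0.372), range 0.0285 to 0.372. Pigment epithelium Tyrp1 (-1.61, SE 0.429) was not called without P6 replicate 2 (adjusted p = 0.0588) or P28 replicate 1 (adjusted p = 0.0558), range 0.000677 to 0.0588. Pigment epithelium Dct (-1.17, SE 0.403) was not called without P6 replicate 2 (adjusted p = 0.165) or P28 replicate 1 (adjusted p = 0.253), range 0.00218 to 0.253, and read -2.05 without P28 replicate 2. Pigment epithelium Mitf (1.01, SE 0.297) was not called without P6 replicate 1 (adjusted p = 0.0551) or P6 replicate 2 (adjusted p = 0.0569), range 0.00134 to 0.0569. Pigment epithelium Rgr (1.22, SE 0.35) was not called without P6 replicate 1 (adjusted p = 0.0808) or P28 replicate 2 (adjusted p = 0.0779), range 0.00112 to 0.0808. Synapse Stx1a (-1.06, SE 0.147) read -0.96 without P6 replicate 2, below the threshold. Leaving out any library did not end the call of endothelium Slco1c1 (1.71, SE 0.335), pigment epithelium Rpe65 (2.67, SE 0.573), cilium Bbs2 (1.08, SE 0.126) and oxidative phosphorylation Sdhd (-1.28, SE 0.103).

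From E11 to E12, 1749 genes were called, 892 higher and 857 lower (1042 and 670 with library size alone, 2004 and 2914 with no fold threshold). The intermediate filament genes Nefm (2.14 ± 0.219 to 77 and 31.9 CPM) and Ina (1.47 ± 0.714 to 48.1 and 20.2) rose most, and Hbb-bh1 (239 and 1710 to 53.3 ± 19.6) and Crym (log2 change -3.75, SE 0.572, or -4.57 without E11 replicate 1 and -1.72 without replicate 2) fell most. Fitted on the compared stages only, these calls were lost (edgeR quasi-likelihood with Benjamini-Hochberg adjusted p = 0.119, 0.143, 0.187 and 0.192), as was that of Hbb-bh1 by DESeq2 (0.713), within ranges of 9.19e-63 to 0.119, 4.2e-51 to 0.143, 8.83e-06 to 0.713 and 1.31e-09 to 0.192. The count depended on single libraries, with 3021 genes without E11 replicate 1, 716 without E11 replicate 2 and 744 without E12 replicate 1, and 7 when only the compared stages were fitted.

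From E12 to E14, 2382 genes were called, 1643 higher and 739 lower (3553 and 1689 with no fold threshold). Islr2, a gene of axon growth, rose from 5.67 ± 1.06 to 214 ± 17.4 (log2 change 5.24, SE 0.241), and the mucin Muc19 from 0.22 and 0.0679 to 23.3 ± 1.86. Hbb-bh1 fell by 5.71 (SE 0.965; edgeR adjusted p = 0.00268, but 0.599 by DESeq2, range 0.00153 to 0.599). Lars2, whose locus takes up ribosomal RNA reads, fell from 13200 ± 51.1 to 498 ± 92.2, and its value is uncertain. Ribosomal RNA made up 0.909% and 1.18% of the counts of the E12 libraries, which also had the lower RNA input, so stage and input changed together in this step. From E14 to E16, 1559 genes were called, 1195 higher and 364 lower (2132 and 1561 with no fold threshold). Chrnb3 rose by 4.79 (SE 0.174), and Syt6, a synaptotagmin, from 0.287 and 0.604 to 21.7 ± 3.65.

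The crystallins Cryaa and Cryga had no counts at E16, and at E14 read 32.6 and 6.03 in replicate 1 and 1080 and 200 in replicate 2. Gamma crystallins are near-identical in sequence, which leaves the reads of Cryga uncertain. The call of Cryaa from E14 to E16 was lost without E14 replicate 2 (edgeR quasi-likelihood with Benjamini-Hochberg adjusted p = 0.193), E16 replicate 1 (0.143) or E16 replicate 2 (0.144), range 1.91e-26 to 0.193. That of Cryga was lost without the same libraries (0.101, 0.0702 and 0.069, range 6.11e-05 to 0.101).

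**Figure D3:**
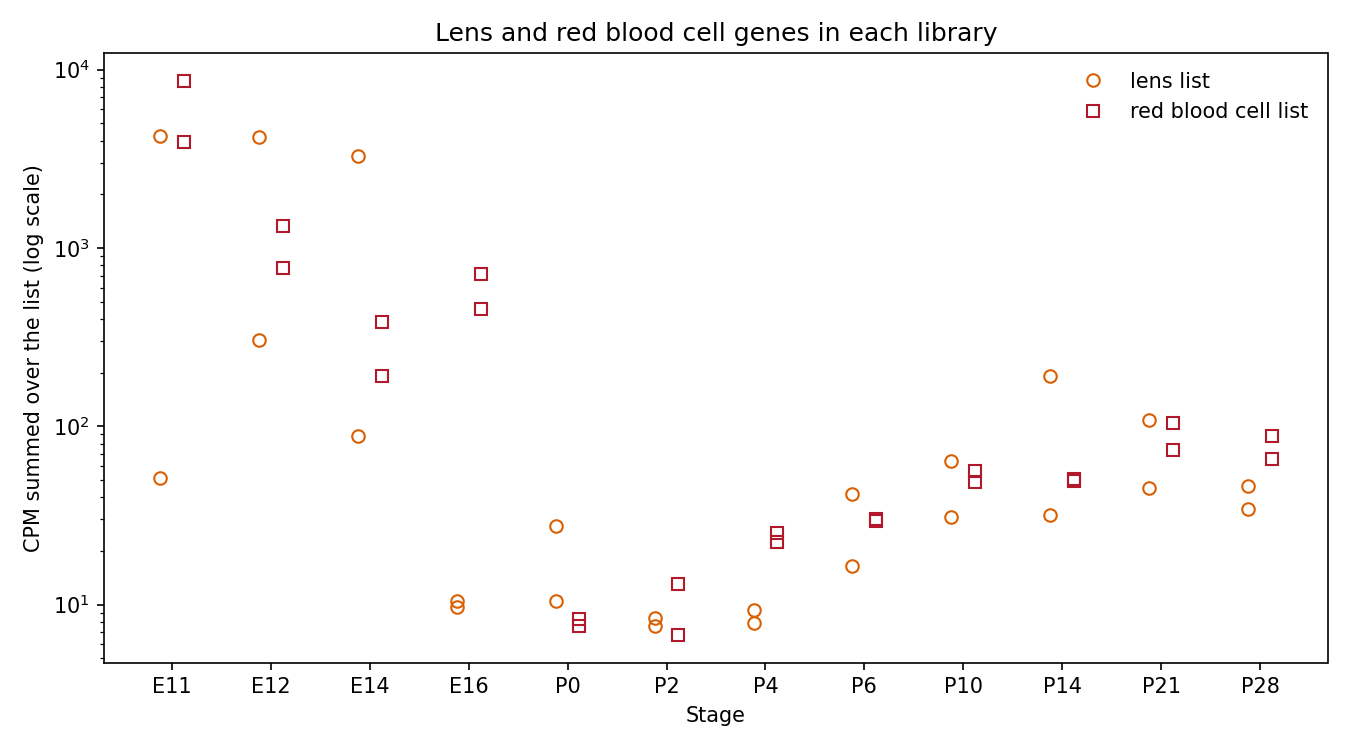
Summed TMM CPM of the lens and red cell lists in each of the 24 libraries.

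From E16 to P0, 1700 genes were called, 1038 higher and 662 lower (2333 and 2432 with no fold threshold). Nr2e3 rose from 0.396 ± 0.0354 to 98 ± 3.74 (log2 change 7.93, SE 0.311) and Pde6b from 3 counts to 23.2 ± 2.08 CPM. The adult globins Hba-a2 (-6.86, SE 0.505) and Hbb-bt (80.8 ± 25.2 to 0 and 0.788) fell most, with reads uncertain between copies. Counts were 1120 without P0 replicate 1 and 1101 without E16 replicate 2. From P0 to P2, 871 genes were called, 661 higher and 210 lower (2302 and 1510 with no fold threshold), or 544 without P0 replicate 2 and 545 with the GC trend removed. The ribosomal protein gene Rpl21 went from 139 ± 0.285 to 34.8 ± 3.76 CPM.

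From P2 to P4, 2459 genes were called, 868 higher and 1591 lower (3338 and 4052 with no fold threshold). This was the highest count of any step, but E14 vs E12 (2382) had more with the GC trend removed (2028 against 1828, with 1949 for P21 vs P14), with glmTreat (808 against 546), with no filter (2778 against 2763), with summed transcript estimates (2463 against 2407) and for protein-coding genes (1919 against 1880). Rps3a2, Rbpsuh-rs3, Pgk1-rs7 and Vcp-rs, among the largest changes of the steps into and out of P2, are copies of other genes, whose values are uncertain since reads cannot be placed between near-identical sequences. Rps3a2 read 0 at both P0 libraries, 152 and 0.737 CPM at P2, and 0 and 0.257 at P4. Rbpsuh-rs3 read 0, 20.6 ± 6 and 0.318 ± 0.223 at P0, P2 and P4, and Pgk1-rs7 23.7 ± 0.826, then 0 and 5.57, then 139 ± 33.7. Vcp-rs went from 0.814 ± 0.0633 at P2 to 39.4 and 7.64 at P4. No call of Rps3a2 held without P2 replicate 1 (edgeR quasi-likelihood with Benjamini-Hochberg adjusted p = 0.409 from P0 and 0.601 to P4, ranges 1.35e-10 to 0.409 and 0.00434 to 0.601). The call from P0 was also lost without P0 replicate 1 (0.106) or 2 (0.127), and that to P4 without P4 replicate 1 (0.115) or 2 (0.0782). Vcp-rs lost its call without P2 replicate 1 (0.0924), P2 replicate 2 (0.0975) or P4 replicate 1 (0.152), range 0.00701 to 0.152. By DESeq2 the calls of Rbpsuh-rs3 did not hold (0.068 from P0 and 0.355 to P4, Benjamini-Hochberg, ranges 7.12e-05 to 0.068 and 4.85e-05 to 0.355), and with only the compared stages that of Pgk1-rs7 from P0 did not (0.0941, range 5.59e-04 to 0.0941).

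From P4 to P6, 571 genes were called, 235 higher and 336 lower (779 and 1021 with no fold threshold). The bipolar genes Grm6 and Vsx1 rose, Grm6 from 0.133 ± 0.052 to 89.9 and 50.2 CPM (log2 change 9.01, SE 0.348) and Vsx1 from 0.266 ± 0.104 to 25 ± 7.06 (6.54, SE 0.326), while Uhrf1 (-2.64, SE 0.213) and the kinetochore gene Ndc80 (-2.61, SE 0.216) fell.

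From P6 to P10, 1720 genes were called, 1003 higher and 717 lower (2382 and 2769 with no fold threshold), with Aqp4 (5.22, SE 0.315) and Abca8a (5.12, SE 0.432) rising and Insm2 (-4.88, SE 0.528) and Mki67 (-3.88, SE 0.209) falling. From P10 to P14, 989 genes were called, 754 higher and 235 lower (76.2% higher, but 62.9% of 952 with library size alone, 2212 higher and 1878 lower with no fold threshold, and 544 called without P10 replicate 2). The non-coding AA474408 (3.77, SE 0.41) and Mir6236 (3.75, SE 0.477), which lies in ribosomal RNA sequence and is uncertain, rose most, and Fabp7 (-1.79, SE 0.186) and the dynein light chain Dynlt1b (-1.60, SE 0.163) fell most. From P14 to P21, 2049 genes were called, 941 higher and 1108 lower (2837 and 3553 with no fold threshold). The cyclase activator Guca1a rose by 3.31 (SE 0.158) and Tecta from 0.742 ± 0.275 to 18.6 and 40.4 CPM, while the fibrillin Fbn2 fell by 3.51 (SE 0.243) and Duxbl1 went from 27.3 ± 3.43 to 0.199 and 1.35.

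From P21 to P28, 194 genes were called, the fewest of any step (329 when only the compared stages were fitted, against 7 for E12 vs E11), 74 higher and 120 lower (597 and 463 with no fold threshold), and 80 of them (41.2%) were protein-coding. Rn18s-rs5 and Lars2, both carrying ribosomal RNA sequence and uncertain, rose most (2.36, SE 0.379, and 2.31, SE 0.326), and Rn18s-rs5 lost its call without P21 replicate 2 (edgeR quasi-likelihood with Benjamini-Hochberg adjusted p = 0.0582, range 1.94e-06 to 0.0582). Tecta went from 18.6 and 40.4 to 0.274 ± 0.0592. Aacs, an enzyme of ketone body use, read 97.3 ± 28.9 and 33 ± 9.09, a call lost without P21 replicate 1 (0.133), P28 replicate 1 (0.131) or P28 replicate 2 (0.0599), and with summed transcript estimates (0.408), range 4.97e-05 to 0.408. The count was 98 without P21 replicate 1, 81 without P21 replicate 2, 85 without P28 replicate 1 and 71 without P28 replicate 2.

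**Figure D4:**
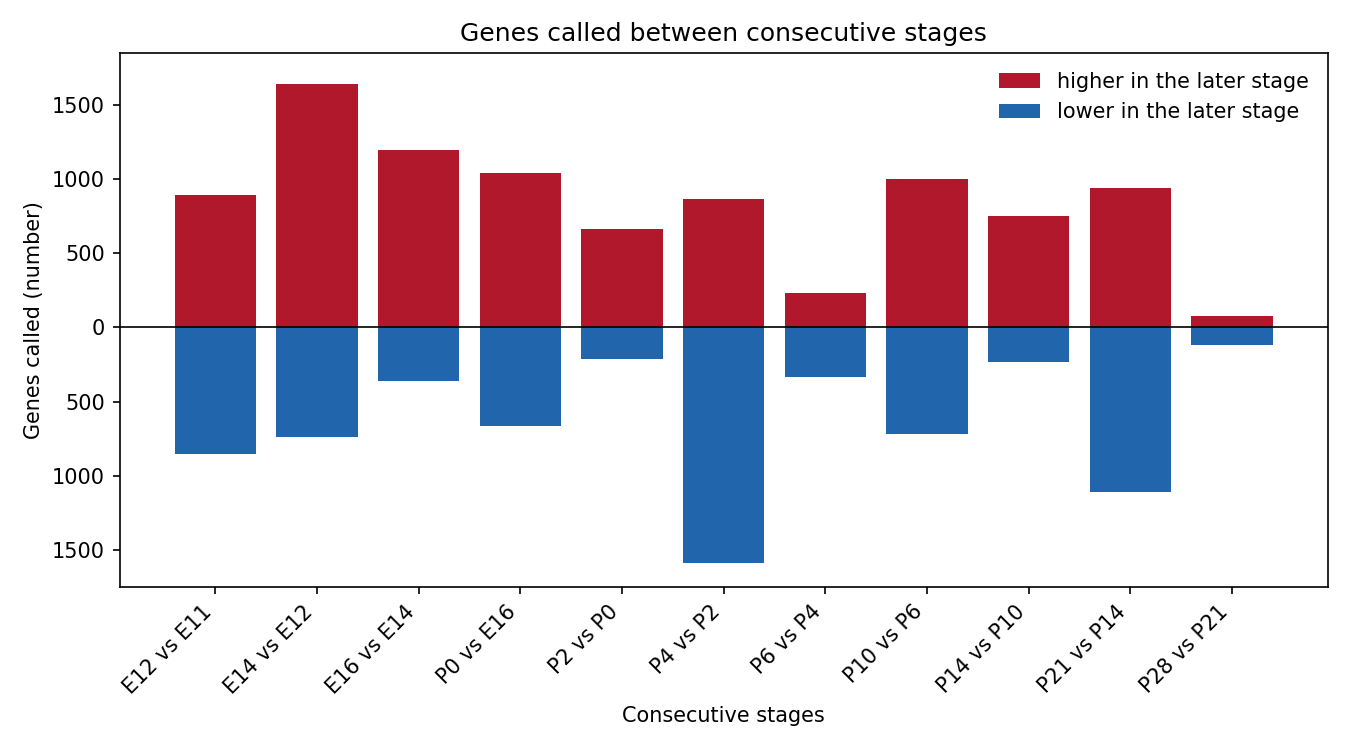
Genes called higher and lower in each of the 11 steps between neighbouring stages.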

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

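Summed transcript estimates, protein-coding genes only, GC removal and the comparisons skipping a stage were tests chosen after the data were seen; the other alternatives of this part were planned. Of 187 alternative counts of calls, leaving out libraries aside, 150 lay within 1.5 times the main count and 37 did not. DESeq2, RLE size factors, library size alone and the stricter filter left each count they covered within 1.5 times.

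The fold settings moved the count of every comparison by over 1.5 times. With no fold threshold, counts were 10014 (E16 vs E11), 10294 (P6 vs E16), 10656 (P28 vs P6) and, step by step from E12 vs E11 to P28 vs P21, 4918, 5242, 3693, 4765, 3812, 7390, 1800, 5151, 4090, 6390 and 1060. With glmTreat they were 2818, 2837 and 2586, and by step 205, 808, 537, 311, 101, 546, 153, 410, 62, 320 and 32. Fitting only the compared stages gave 7 for E12 vs E11, the largest shift of any setting, and 329 for P28 vs P21. P28 vs P21, with 194 calls, also moved with no filter (429), transcript sums (106), protein-coding genes (86) and GC removal (115), and P28 vs P14 gave 1936. GC removal took P2 vs P0 from 871 to 545.

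Without 1 library, counts ran from 716 (without E11 replicate 2) to 3021 (without E11 replicate 1) for E12 vs E11, from 1101 (without E16 replicate 2) to 1574 for P0 vs E16, from 544 (without P0 replicate 2) to 771 for P2 vs P0, from 544 (without P10 replicate 2) to 994 for P14 vs P10, and from 71 (without P28 replicate 2) to 98 for P28 vs P21. Of 88 such counts 77 lay within 1.5 times.

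Of the 87 list tests 46 passed, and 26 with an estimated correlation. Over 435 alternatives 389 gave the same side of the threshold and direction, 22 lost it and 24 gained it. Without 1 library these were 338, 2 and 8 of 348. For 337 results of named genes, 2610 of 2677 alternatives kept the call and 67 lost it, and without 1 library 1200 of 1348 kept it and 147 lost it. Slc2a3 in E16 vs E11 changed sign (log2 change 0.39 without E11 replicate 2, adjusted p = 0.366 by edgeR quasi-likelihood with Benjamini-Hochberg, and -1.91 without E11 replicate 1, adjusted p = 2.95e-05). The 29 genes followed over the stages kept their omnibus call in all 203 alternatives and all 696 fits without 1 library. With library size alone 477 of 516 list members had the same peak stage.

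A replicate block changed the counts to 4928 (E16 vs E11), 5432 (P6 vs E16) and 5364 (P28 vs P6). Replicates share only a number: over 66 stage pairs the correlation of replicate differences ran from -0.057 to 0.13 (median 0.0042), with 2 pairs over 0.1.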

Other observations

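The tests chosen only after the result was seen are the choice of stage-restricted genes, removal of the GC trend (for GC content as part and as the whole cause), P4 vs P0 skipping P2, lens tissue and a mislabelled sample at E14. Some genes stood higher at an age than at every stage beyond its neighbours. The peak had to reach 20 CPM, and its lower library 2 times each mean beyond the neighbouring stages. There were 211 such genes at P21, 58 at P2, 45 at E12 and 40 at E14, against 7 at P0 and 8 at P10. E11 and P28 were not scored as peaks. At E12 and P21 the stages beyond lie on a single side, so these counts are not comparable with those of the middle stages. Genes that stay high to P28, such as Guca1b (mean 1050 CPM there), count at P21. In 206 of the 211 at P21 a neighbouring stage had a mean over 0.5 of the peak. Lens genes added 3 of the 45 at E12, such as Mip (82.4 ± 95.5 CPM), and none of the 40 at E14, and in 4 and 0 the libraries were at least 2-fold apart. Capn3 (126 ± 121) also differed between the E12 libraries. Sfrp2, a Wnt pathway inhibitor, stood at 1340 ± 124 CPM and Mecom at 93.1 ± 1.21 at E12 (SD, n = 2). At E14 the axonal adhesion gene Cntn2 (336 ± 6.86), the neuropeptide gene Gal (25.8 ± 1.96) and Dlx2 (28.7 ± 2.56) peaked, and at E16 Fgf3 (49.4 ± 1.15), Pou3f1 (26.6 ± 0.583) and the somatostatin receptor Sstr2 (32.1 ± 1.01). Hs3st4 (85.1 ± 3.32) peaked at P0, Tagln2 (176 ± 16.8), St14 (44.2 ± 0.763) and Cnp (112 ± 5.11) at P2, Gngt2 (262 ± 6.28), Dbi (331 ± 26.5) and Sat1 (321 ± 8) at P4, and Gal3st4 (53.5 ± 2.91) and Tmem86a (108 ± 1.84) at P6. Psd2 (233 ± 13.3) and Vcam1 (58.9 ± 1.78) peaked at P10, the thyroid hormone deiodinase Dio2 (94 ± 2.4), Abcc9 (31.9 ± 0.572) and Tmem229b (381 ± 38.4) at P14, and Kcnj14 (543 ± 9.82), Guca1b (1190 ± 26.6) and Guca1a (463 ± 29.3) at P21. P2 and P21 are also the stages with the steepest rise of log2 values with GC content (0.343 and 0.283 per 10 percentage points).

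More genes were called between P2 and P4 (2459) than between P0 and P2 (871) or P4 and P6 (571). The fitted GC trend as the whole cause is argued against: with it removed the count was 3.11 times the larger neighbouring count (1828 against 588). Other GC bias was not tested. GC bias of the P2 and P4 libraries as part of the cause cannot be told apart from other causes. The count without the trend was 0.743 of the main one, between the bounds set for either outcome. The genes also differed, with 1423 of the 2459 calls among those 1828. Reads shared between pseudogenes and their parent genes cannot be told apart either: 0.766 of the calls were protein-coding genes on the chromosomes, but so were 0.753 of the genes tested, and parent genes are protein-coding themselves, so the bound of 0.75 set beforehand decides nothing. A burst of developmental change may also contribute, but P4 vs P0 called 0.96 times as many genes as P4 vs P2 (2361), which leaves it open too.

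Lens genes differed many-fold between replicates at E11, E12 and E14, with summed CPM of 4230 against 51.3, 4200 against 304 and 3300 against 88.2. Lens tissue in some libraries cannot be told apart from other causes that raise lens genes together: 60 of 61 lens members counted (98.4%) were at least 2-fold higher in the library with the higher sum, but the same members pick that library. A mislabelled sample at E14 is argued against, since 0 of its 2 libraries correlated best with another stage (Spearman correlation 0.987 within E14). An exchange of E11 replicate 1 with E12 replicate 1 is argued against by E11 replicate 2 and E12 replicate 1, whose correlation (0.9535) differed by -0.0248 from the weaker pair within a stage. A mislabelled sample at E11 or E12 cannot be told apart from nearby ages or lens tissue. Without the lens list 2 of the 6 libraries correlated best with another stage. These were the lens-rich E11 replicate 1 and E12 replicate 2 (0.9821, against 0.9784 and 0.9804 within their stages).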
